A study of Mus musculus with 3 samples.

How the data were processed

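Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map binding of the transcription factors Tbx4 and Hoxc10 in hindlimb buds of wild-type CD1 mouse embryos at embryonic day 11.5. Per the labels' protocols, the tissue was fixed with formaldehyde, nuclei were isolated, the DNA was sheared by sonication and the protein-bound fragments were pulled down with an antibody. The labels give 3 samples in 3 groups of 1: a Tbx4 ChIP with a homemade antibody, a Hoxc10 ChIP with an Abcam antibody and a Hoxc10 ChIP with a Santa Cruz antibody. The Santa Cruz sample was not analysed here. Each of the other samples is represented by 1 peak list, so there are no replicates. Every p-value below describes the sites or genes of these 2 lists, not the spread between embryos or experiments.

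Per the submitters' processing notes, the tools were Bowtie2 2.2.6 for alignment, MACS2 2.1.1.20160309 for peak calling and HOMER, on the mouse genome build mm10. The deposited files list peak summits of 1 bp, 4780 for Tbx4 and 1614 for Hoxc10. The score that the authors deposited beside each summit is the value of MACS2 on a −log10 scale. Whether it is the −log10 of a p-value or of a q-value is not given in the sources used here. It was used to describe, rank, filter or compare sites within 1 list. At shared sites the scores of both lists were also correlated, and their ranks combined to pick the best-ranked sites. Score levels were not compared between the lists. The peak names carry the running numbers of MACS2, which rise with position on every chromosome. The highest number is 45103 in the Tbx4 list and 4026 in the Hoxc10 list, so the lists hold 10.6% and 40.1% of the numbers, and most of the numbered peaks are not among the sites used here. How they were selected, which control library was used and whether libraries were pooled are not given in the sources used here. The names of the lists carry abbreviations that no label explains, so that a selection on repeats and on excluded regions remains possible. For Hoxc10 the wording may mean that only Abcam sites within 200 bp of peaks of the Santa Cruz antibody were kept. Read depth is unknown, since the files hold no read counts, and no library without a specific antibody was used here.

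Genes came from a table of the GRCm38 assembly, the same build as mm10, with 21883 protein-coding genes on the primary chromosomes. This table has gene starts and ends but no strand and no transcripts, and no genome sequence was used here. The planned tests were therefore adapted. A transcription start was replaced by either end of a gene, and exons, introns and untranslated regions were not told apart. The planned motif and k-mer tests were not run. A gene's domain was the gene with 1 kb to each side, extended both ways to the nearest such region of a neighbouring gene and by at most 1 Mb, with a median length of 65.7 kb. A site between 2 genes thus counts for both of them. Coordinates are given 1-based on mm10.

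Sites of both factors were called shared when their summits lay within 200 bp. The expected share came from 10000 draws in which each Hoxc10 site was moved by its own random distance of 5 to 100 kb, and the smallest two-sided p these draws can give is 0.0002. The same shifts gave the expected share of sites within 1 kb of a gene end. Shares were compared with Fisher's exact test (two-sided), and medians of the score with a two-sided permutation test of 100000 resamples, whose smallest p is 1e-05. Intervals of shares are 95% Wilson intervals and intervals of median differences come from 2000 bootstrap resamples of sites.

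Before the data were examined, 16 gene lists with 418 distinct genes were fixed for limb patterning, tissues of the limb bud, signalling pathways, other cell types and controls. All 418 were matched to the gene table, 1 of them by a synonym. List membership was permuted: for each list and factor, the number of genes with at least 1 site in their domain was compared with 10000 random lists of the same size, drawn from all protein-coding genes and matched on domain length in 20 bins. The random lists could hold genes of chromosomes X and Y, where few sites were kept. The 32 p-values were adjusted by the Benjamini-Hochberg method. The share of sites in the domains of a list was compared between the factors with Fisher's exact test, adjusted over 16 lists. Named are the nearest genes of the 10 highest-scoring sites of each factor and of the 10 best-ranked shared sites, the 5 genes with the most sites of each factor, the 3 genes with the most sites of each list (up to 5 for the limb and Hox lists), and Tbx4, Hoxc10 and Pitx1. This rule was fixed before the data were examined; some genes it names are not reported here.

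The tests were tried on simulated data. Of the Hoxc10 sites, planted shares of 0, 10 and 30% next to Tbx4 sites were recovered as 0.139, 10.1 and 30.1%, and 5, 100 and 100% of 20 runs passed 0.05. With no planted sites the gene list test passed 0.05 in 3% of 100 runs for Tbx4 and 1% for Hoxc10, and with sites planted at 30% of the listed genes in 88% and 97%. The simulated lists were random draws from all genes. They do not show how the test behaves for lists of neighbouring genes that share sites, such as the Hox genes. The test of medians passed in 0% of 40 runs for Tbx4 and 2.5% for Hoxc10 with no difference, and in 100% and 97.5% with 2 score units added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the distance that counts as shared, stricter scores, other shifts, other distances from a gene end, other domains and a binomial test on sites.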

Results

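Binding of 2 factors of the developing hindlimb was profiled by ChIP-seq in hindlimb buds of mouse embryos. Tbx4 is a T-box factor expressed in the hindlimb and not in most of the forelimb, and Hoxc10 is a homeodomain factor of the posterior Hox genes. The Tbx4 list held 4780 sites, with a median MACS2 score of 3.67 (quartiles 2.94 and 7.14, highest 317.1). The Hoxc10 list, from the Abcam antibody and possibly limited to sites near peaks of the Santa Cruz antibody, held 1614 sites with a median score of 7.72 (quartiles 5.05 and 12.99, highest 237.9). Each list stands for 1 sample, there are no replicates, and the read depth is unknown.

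The first comparison asked how far Tbx4 and Hoxc10 occupied the same places in hindlimb chromatin. Of the 1614 Hoxc10 sites, 518 had a Tbx4 summit within 200 bp, or 32.1% (95% interval 29.9 to 34.4%). These made up 10.9% (10.01 to 11.8%) of the Tbx4 list, 519 sites. When the Hoxc10 sites were moved locally, 0.213% of them fell next to a Tbx4 site (95% of draws between 0 and 0.434%), so that the observed share was 150-fold higher (permutation p = 0.0002, the smallest the draws can give). The fold depended on the setting, from 37.3 at 1000 bp and 71.2 at 500 bp to 241 with shifts of 100 kb to 1 Mb and 413 with random places on the chromosome. Shared summits lay close together, at a median of 63.5 bp (quartiles 28 and 105), and 218 Hoxc10 sites were within 50 bp of a Tbx4 summit. Only 109 more had their nearest Tbx4 site between 200 and 1000 bp away. Among the 50 highest sites of each list the shared part was 60% for Hoxc10 (30 sites, interval 46.2 to 72.4%), against 32.1% of the list, and 40% for Tbx4 (20 sites, 27.6 to 53.8%), against 10.9%. When both lists were limited to their higher-scoring 50%, 27.3% of the Hoxc10 sites were shared.

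**Figure D1:**
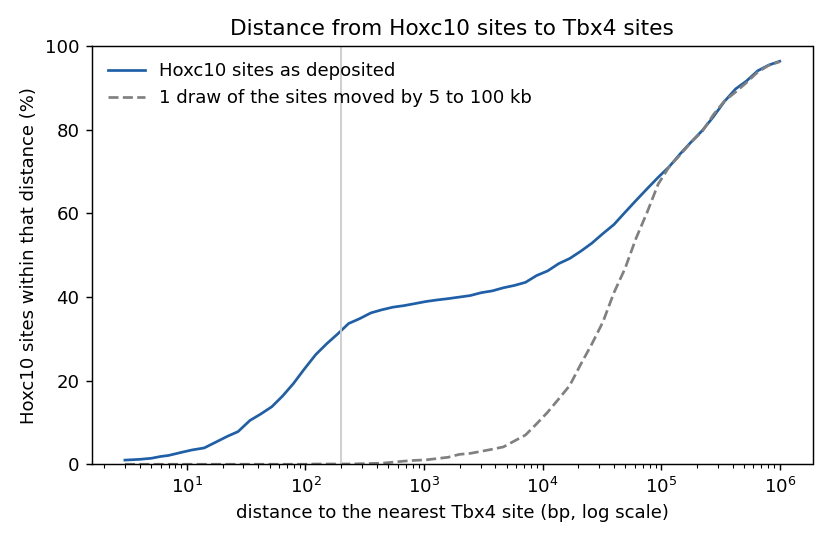
Share of the 1614 Hoxc10 sites (vertical axis, percent) whose nearest Tbx4 site lies within a given distance (horizontal axis, bp, log scale), as deposited and after 1 draw of local shifts; the grey line marks 200 bp. The observed curve reaches 32.1% at 200 bp and 38.9% at 1000 bp, while the shifted sites stay near 0 at 200 bp.

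The strongest shared site lay on chromosome 15 outside the gene Gpr84, a receptor for medium-chain fatty acids, 2804 bp from its nearer end. Its Tbx4 summit at 103305429 had the highest score of that list, 317.1, and its Hoxc10 summit 16 bp away scored 178.7. The highest-scoring Hoxc10 site, at position 173171698 of chromosome 2, was 12424 bp from Pck1, which encodes an enzyme of gluconeogenesis. It scored 237.9, with a Tbx4 summit of 50.96 at a distance of 60 bp. Inside Hoxa9 both summits fell within 2 bp of each other, at 52226296 and 52226298 of chromosome 6, with scores of 48.91 for Hoxc10 and 62.04 for Tbx4. A shared site 15788 bp from Col1a2, a chain of type I collagen, scored 135.4 for Tbx4 and 31.58 for Hoxc10. Another, 205594 bp from Osr1, a factor of the limb's connective tissue lineages, scored 104 for Hoxc10 and had its Tbx4 summit 11 bp away. Further high shared sites lay inside Iqca (Tbx4 104.5, Hoxc10 36.79) and Uvrag (34.51 and 81.66). Others lay outside genes, with the nearest gene end often far away. The Hoxc10 summits were 133741 bp from Lnpk (63.65 and 35.74) and 219257 bp from Spag17 (95.7 and 32.61). They were 55033 bp from Cep85l (27.52 and 41.1) and 5097 bp from 1700122O11Rik (44.83 and 54.67).

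Other top sites had no partner. The Tbx4 sites next in score to that at Gpr84, inside Hsd11b2 (chromosome 8, 105519815, score 249.7) and inside Trio (chromosome 15, 27742072, score 247.6), had no Hoxc10 site within 200 bp. Hsd11b2 encodes an enzyme that inactivates glucocorticoids and Trio a guanine nucleotide exchange factor. Unshared too were Tbx4 sites inside Cntfr (126.2), inside Rnf24 with Pank2 as the nearest gene end (124.4) and 263429 bp from Nsun3 (104.5). So were Hoxc10 sites 7729 bp from Ubl4b (140.3) and inside Tcf7l1 (60.58). The remaining top Hoxc10 sites, all shared, were nearest to A430057M04Rik (90.72), Tanc1 (86.81), Zfp703 (85.52) and Ly86 (80.38), and a shared Tbx4 site lay inside Pknox2 (152.4), which encodes a homeodomain partner of Hox proteins.

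Tbx4 and Hoxc10 sites differed in their distance from genes. Of the Tbx4 sites 614, or 12.8% (11.9 to 13.8%), lay within 1 kb of an end of a protein-coding gene, compared with 81 Hoxc10 sites, or 5.02% (4.06 to 6.20%), a difference of 7.83 percentage points (Fisher's exact test, p = 8.8e-21). Local shifts gave 3.48% and 2.22%, so that both factors were closer to gene ends than shifted sites, by 3.69-fold for Tbx4 and 2.26-fold for Hoxc10 (permutation p = 0.0002 for each). Hoxc10 sites were more often over 100 kb from any gene end, 39.2% (36.8 to 41.6%) against 29.2% (28.0 to 30.6%) of Tbx4 sites, and less often inside a gene, 38.9% against 46.5% (Fisher's exact test, p = 9.7e-08). The difference near gene ends shrank to 2.67 points in the higher-scoring 50% of each list (8.49% against 5.82%, Fisher's exact test, p = 0.0151) and to 2.35 points when the 1614 highest Tbx4 sites were used (7.37%, p = 0.00678).

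Sites that both factors shared were rare at gene ends. Of the shared Tbx4 sites 1.54% (8 of 519) lay within 1 kb of a gene end, against 14.2% (606 of 4261) of the unshared ones (Fisher's exact test, p = 1.7e-22). For Hoxc10 the shares were 1.54% (8 of 518) and 6.66% (73 of 1096; Fisher's exact test, p = 2.3e-06). Shared sites also had higher scores. The median Tbx4 score was 7.14 at shared and 3.67 at unshared sites, a difference of 3.47 (95% interval 2.52 to 4.45; permutation p = 1e-05, the smallest possible). The median Hoxc10 score was 8.96 against 7.36, a difference of 1.6 (0.71 to 2.14; permutation p = 2e-05). Across the 518 shared sites, which are not independent replicates, the scores of both factors were weakly related (Spearman's rho = 0.178, permutation p = 6e-05; Pearson's r = 0.404, p = 0.00024). Without the 2 sites farthest from the median, r was 0.163 (p = 0.00218) and rho 0.169 (p = 0.00012).

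The next comparison asked which genes lay around the sites. Genes of limb patterning and hindlimb identity were bound more often than random genes with domains of the same length. For Tbx4 the same held for the housekeeping control genes, described below. Their ratio of observed to expected genes was 3.31, against 1.96 for limb outgrowth and patterning signals. A Tbx4 call in this test is thus not particular to limb genes. In the list of limb outgrowth and patterning signals, 35 of 53 genes had a Tbx4 site where 17.9 were expected (adjusted permutation p = 0.000711), and 21 had a Hoxc10 site against 9.82 (adjusted p = 0.000914); 18 genes had both and 11 had a shared site. Among them were Lmx1b, which specifies dorsal limb identity (7 Tbx4 sites and 1 Hoxc10 site), Hand2, which acts upstream of Shh in the posterior bud (7 and 2), Fgfr2, a receptor for the growth factors of bud outgrowth (8 and 3), Tbx3 (8 and 2) and Bmp4 (5 and 2). Another 15 genes had sites of neither factor, among them the signals Shh, Fgf8, Fgf4, Grem1 and Wnt7a. Fgf10 had 0 Tbx4 sites and 1 Hoxc10 site. A domain stops at the neighbouring gene, so sites inside or beyond a neighbour were not counted for these genes. A count of 0 thus does not show that distant regulatory elements of a gene were unbound. The Hoxc10 call ended when sites were given to the nearest gene within 100 kb (10 genes, 4.65 expected, adjusted permutation p = 0.0552). The ratio of observed to expected genes was 2.15 there, against 2.14 in the main setting. In the list of hindlimb and forelimb identity, 12 of 19 genes had Tbx4 sites against 3.93 expected (adjusted permutation p = 0.000914) and 9 had Hoxc10 sites against 1.78 (adjusted p = 0.000711). Without the 9 Hox cluster genes of this list, which are also in the Hox list, 7 of 10 had Tbx4 sites (3.06 expected, adjusted permutation p = 0.022) and 5 of 10 Hoxc10 sites (1.68 expected, 0.0251), and the ratio for Hoxc10 fell from 5.05 to 2.98. Hox genes of 1 cluster share sites, so the p-values of the list with them are too small.

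The gene for Tbx4 itself had 6 Tbx4 sites and 3 Hoxc10 sites in its domain. The highest, with a score of 54.08, lay at 85886288 of chromosome 11, just outside the lower end of the gene at 85886367. The Hoxc10 gene had 2 Tbx4 sites, with a best score of 10.21, and 0 Hoxc10 sites. Pitx1, the upstream determinant of hindlimb identity, had 0 Tbx4 sites and 1 Hoxc10 site, at 55962569 of chromosome 13 with a score of 5.69. Isl1, needed to start the hindlimb bud, had 4 Tbx4 and 2 Hoxc10 sites, and Nrip1 4 and 1.

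**Figure D2:**
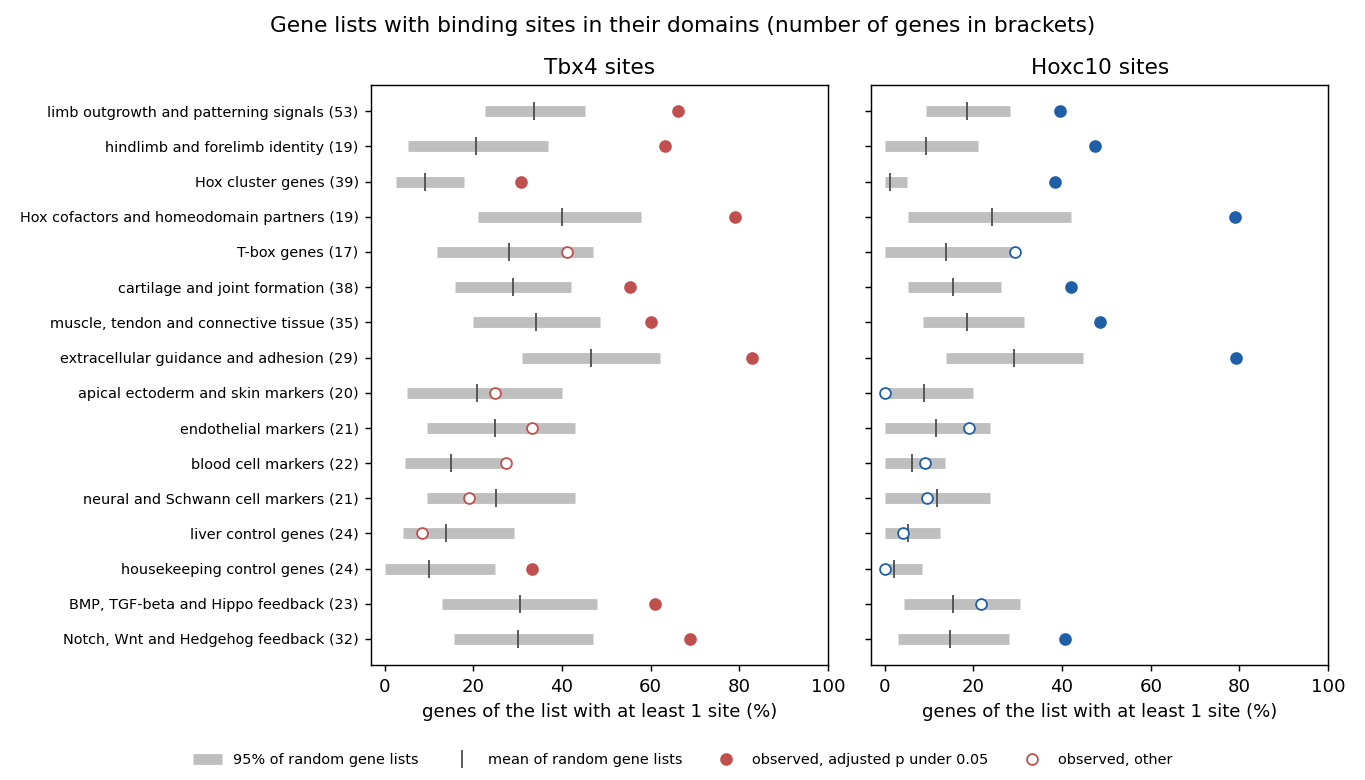
Percent of the genes of each list (number in brackets) with at least 1 Tbx4 site (left) or Hoxc10 site (right) in their domain; points are observed shares, grey bars hold 95% of 10000 random gene lists matched on domain length, and ticks are their means. Filled points, with adjusted p under 0.05, appear for 10 lists with Tbx4 and 8 with Hoxc10.

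Skeletal, connective tissue and guidance genes were also bound by both factors. Of 38 cartilage and joint genes 21 had Tbx4 sites (10.99 expected, adjusted permutation p = 0.000914) and 16 Hoxc10 sites (5.85, adjusted p = 0.000711). Sox9, the main regulator of cartilage formation, had 17 Tbx4 and 7 Hoxc10 sites, 4 of them shared; its partner Sox5 had 11 and 3, and Trps1 9 and 7. Of 35 muscle, tendon and connective tissue genes 21 had Tbx4 sites (11.9 expected, adjusted permutation p = 0.0028) and 17 Hoxc10 sites (6.53, adjusted p = 0.000711). There were 11 and 4 at Osr1, 7 and 6 at Cdh2, an adhesion molecule of mesenchyme, and 14 and 4 at Tcf4. Tcf4 here is the gene of that symbol and not Tcf7l2, a separate list member with 5 and 4 sites. Of 29 genes for extracellular guidance and adhesion 24 had Tbx4 sites (13.5 expected, adjusted permutation p = 0.000914) and 23 Hoxc10 sites (8.47, adjusted p = 0.000711), with 6 and 3 at the ephrin receptor Epha4, 7 and 4 at the repellent Sema3a and 5 and 5 at Efna5. The Hoxc10 calls ended under other domains for cartilage genes (adjusted permutation p = 0.0655 with the nearest gene, 0.086 with the gene and 5 kb to each side) and for guidance genes (0.134 with the latter). The ratios of observed to expected genes there were 2.515 and 2.406 for cartilage genes, against 2.734 in the main setting. For guidance genes the ratio was 1.939 against 2.714.

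Feedback and response genes of signalling pathways were bound by Tbx4 more often than random genes, and those of 1 list also by Hoxc10. Of 32 genes of the Notch, Wnt and Hedgehog pathways 22 had Tbx4 sites (9.65 expected, adjusted permutation p = 0.000711) and 13 had Hoxc10 sites (4.73, adjusted p = 0.000914). The Notch target Hes1 had 10 and 2 sites, and the Hedgehog co-receptors Gas1 and Boc had 8 and 4, and 5 and 2. Of 23 genes of BMP, TGF-beta and Hippo feedback 14 had Tbx4 sites (7.04 expected, adjusted permutation p = 0.00489), a call that ended in the higher-scoring 50% of sites (8 genes, adjusted p = 0.193), with the nearest gene (9 genes, 0.0697) and in the binomial test on sites (20 sites, 0.196). The ratio of observed to expected was 1.99 in the main setting and 1.735, 2.015 and 1.406 in these settings. Only 5 had Hoxc10 sites (3.54 expected, adjusted permutation p = 0.677). Tead1, the DNA-binding partner of Yap1, had 4 and 1, and Smad6 and Id2 had 2 and 1, and 2 and 2. Among 17 T-box genes, 7 with Tbx4 sites and 5 with Hoxc10 sites did not pass the test (4.79 and 2.34 expected; adjusted permutation p = 0.463 and 0.19), although single members held many sites: Tbx18 16 and 9, and Tbx15 15 and 6. A binomial test that counts sites in place of genes called this list for both factors (48 Tbx4 sites, adjusted p = 1.2e-18; 21 Hoxc10 sites, 6.9e-11). By genes, Hoxc10 passed in the higher-scoring 50% of sites (5 genes, adjusted permutation p = 0.026) and with the gene and 5 kb to each side (3 genes, 0.0136).

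No list of markers of other cell types passed the test by genes for either factor. Tbx4 sites were found at 5 of 20 ectoderm genes (4.19 expected, adjusted permutation p = 0.911), among them Cdh1, Grhl3 and Tfap2c, at 7 of 21 endothelial genes (5.24, 0.616), at 6 of 22 blood genes (3.28, 0.227), at 4 of 21 neural and Schwann cell genes (5.28, 0.821) and at 2 of 24 liver genes (3.33, 0.764). The Hoxc10 counts were 0 (1.76 expected, adjusted permutation p = 0.42), 4 (2.46, 0.576), 2 (1.36, 0.911), 2 (2.47, 1) and 1 (1.25, 1). Most sites in these lists fell to the endothelial genes Ets1 (8 and 1), Fli1 (4 and 2) and Cdh5 (3 and 0), to the blood list's Runx1 (7 and 3), also a cartilage list member, and to Sox2 (6 and 0). Counted by sites, the binomial test called the endothelial and blood lists for Tbx4 (adjusted p = 0.0243 and 0.0129). Housekeeping genes, listed as a control, passed the test for Tbx4, with sites at 8 of 24 (2.42 expected, adjusted permutation p = 0.00533). There were 4 sites at Ywhaz and 2 each at Canx and Polr2a. No Hoxc10 site lay at these 24 genes, where 0.517 genes were expected to have one, and the difference in the share of sites between the factors did not pass after adjustment (Fisher's exact test, adjusted p = 0.193). Without sites in 1 kb of a gene end, 2 housekeeping genes had Tbx4 sites (1.42 expected, adjusted permutation p = 0.959). The list of limb outgrowth and patterning signals still passed there for Tbx4 (34 genes, 17.1 expected, adjusted permutation p = 0.000533).

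Some genes gathered many sites. Zfp608 had 26 Tbx4 and 17 Hoxc10 sites, Mgmt 21 and 11, Zfp703, a corepressor gene, 19 and 21, Lrmda 18 and 16, Mki67 17 and 11, Thap1 17 and 18, and Gramd3 12 and 11. Neighbouring genes share the sites between them, as Zfp703 does with Thap1, Mki67 with Mgmt, Zfp608 with Gramd3 and Tbx15 with Spag17. In the domain of Zfp703, from 26165152 to 27022370 of chromosome 8, 9 of the Hoxc10 sites had a Tbx4 site within 200 bp. The highest was a Hoxc10 summit of 85.52 at 26914355.

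**Figure D3:**
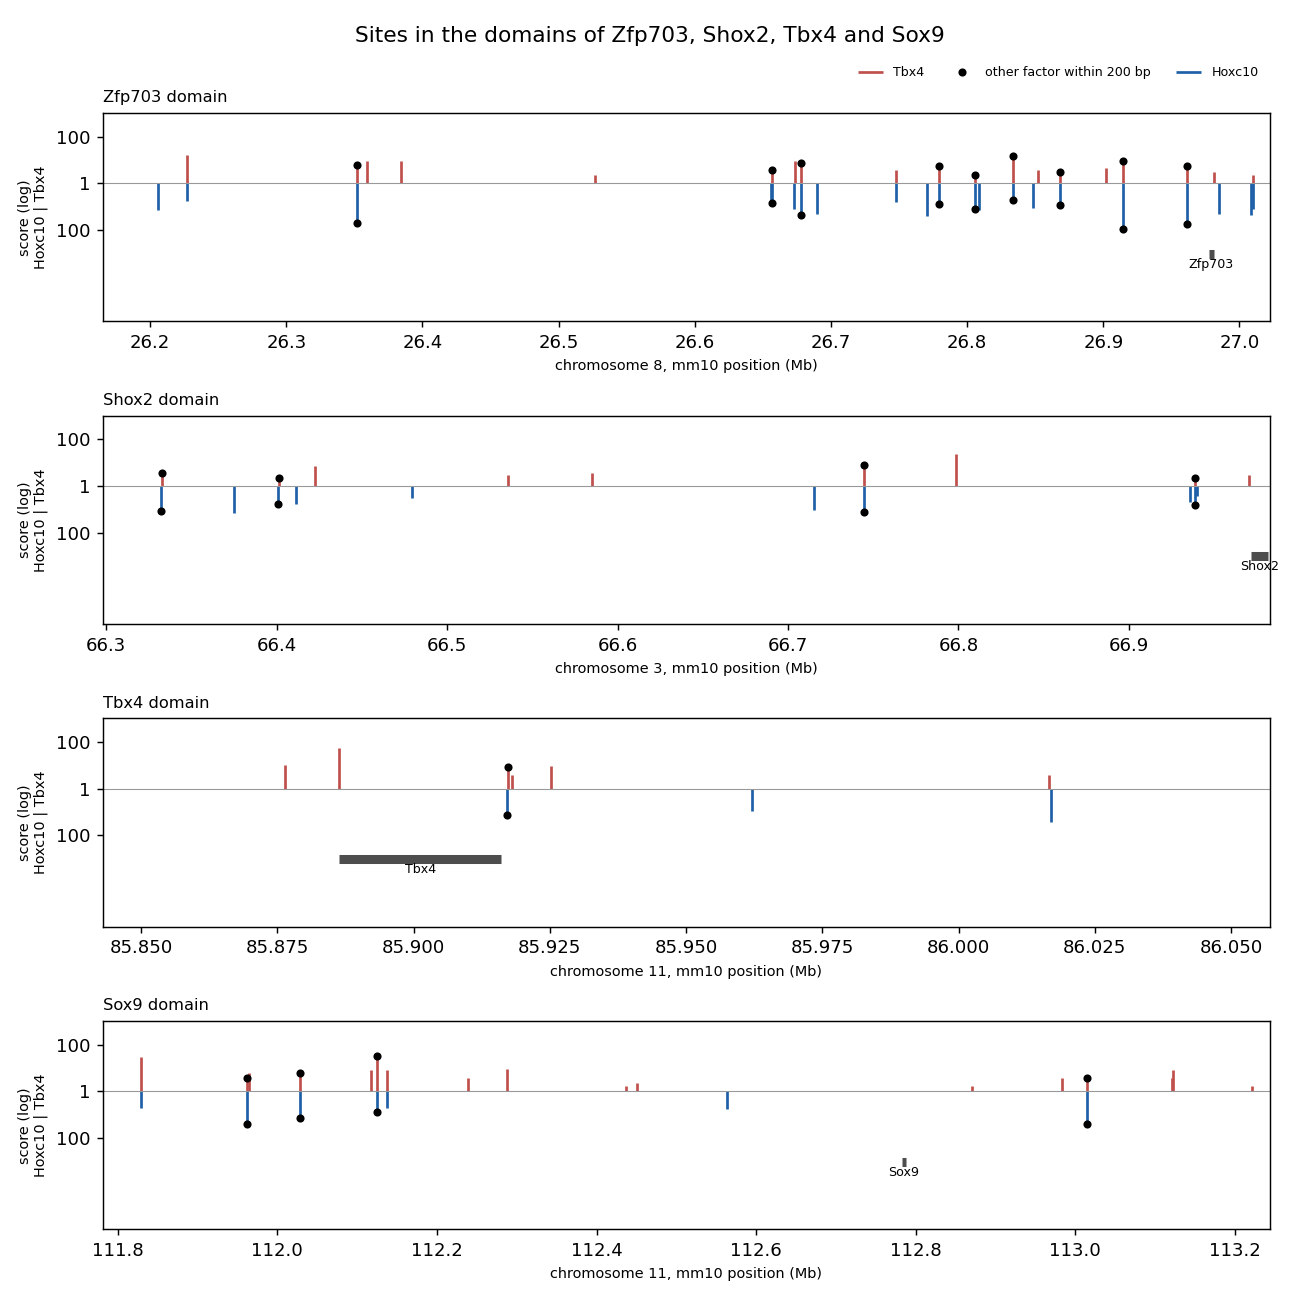
Sites in the domains of Zfp703, Shox2, Tbx4 and Sox9 along mm10 (horizontal axes, Mb), with bars up for Tbx4 and down for Hoxc10, their length the MACS2 score of each list on a log scale; scores of different lists are not comparable. Black points mark sites with the other factor within 200 bp (9 Hoxc10 sites at Zfp703, 4 at Shox2, 1 at Tbx4 and 4 at Sox9), and grey blocks are protein-coding genes.

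With all sites, the lists of Hox cluster genes and of Hox cofactors and homeodomain partners took a larger share of Hoxc10 than of Tbx4 sites. In domains of the 39 Hox cluster genes lay 20 Hoxc10 sites, 1.24% of the list, and 15 Tbx4 sites, 0.314%, a difference of -0.925 percentage points (Tbx4 minus Hoxc10; Fisher's exact test, adjusted p = 0.00149). By genes, 15 of 39 had a Hoxc10 site (0.509 expected, adjusted permutation p = 0.000711) and 12 a Tbx4 site (3.59, adjusted p = 0.00128). The Hox genes stand in 4 clusters and neighbours share sites, so they are not independent and the p-values by genes are too small. Domains of Hox cofactors and homeodomain partners held 3.16% of Hoxc10 and 1.63% of Tbx4 sites (-1.53 points, Fisher's exact test, adjusted p = 0.0023), although each factor had sites at 15 of these 19 genes (4.60 and 7.59 expected, adjusted p = 0.000711 for both). There Shox2, needed for the proximal limb skeleton, had 9 Tbx4 and 10 Hoxc10 sites, the Hox cofactor Meis1 8 and 5, and Irx3 8 and 4. Hox cofactors were not tested apart from other members such as Shox2, Irx3 and Tshz1, so the difference belongs to the whole list. Guidance and adhesion genes held 2.85% and 1.42% (-1.43 points, Fisher's exact test, adjusted p = 0.0023), and the shares of the other 13 lists did not pass the adjusted test. With the 1614 highest Tbx4 sites the 3 differences were -0.806, -1.30 and -1.12 points and did not pass (Fisher's exact test, adjusted p = 0.191, 0.191 and 0.239). With domains of up to 50 kb only that of the Hox genes passed. With 1 site per gene domain that of the list of cofactors and homeodomain partners did not (Fisher's exact test, adjusted p = 0.0712).

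Inside the 4 Hox clusters, 492 kb in all, there were 18 Hoxc10 and 10 Tbx4 sites, where their length alone would give 0.292 and 0.864 (exact binomial test, p = 2.5e-26 and 2.9e-08). As a share of each list this was 1.12% and 0.209% (Fisher's exact test, p = 1.4e-05). With the 1614 highest Tbx4 sites it was 1.12% and 0.372% (6 Tbx4 sites, Fisher's exact test, p = 0.0222). These tests inside the clusters were chosen after the data were seen and are not adjusted. For the domains of the Hox genes above, the same Tbx4 sites gave p = 0.0187 before and 0.191 after adjustment (Fisher's exact test). The smaller p-value inside the clusters is thus no separate support. Hoxc10 sites numbered 7 in the Hoxa, 4 in the Hoxb, 4 in the Hoxc and 3 in the Hoxd cluster, against 3, 1, 3 and 3 Tbx4 sites. Hoxa3 had 4 Hoxc10 and 0 Tbx4 sites in its domain, Hoxb3 2 and 1, and Hoxd3 2 and 2. In the gene coordinates used, Hoxa3 spans Hoxa4, Hoxa5 and Hoxa6, Hoxb3 spans Hoxb4, and Hoxd3 spans Hoxd4. These counts thus do not tell such genes apart from the genes they span. The 3 shared sites lay inside Hoxa9, inside Hoxb3 near Hoxb4 (chromosome 11, 96326148, scores 13.86 for Hoxc10 and 11.3 for Tbx4) and inside Hoxc5 (chromosome 15, 103014638, 43.3 and 20.91).

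**Figure D4:**
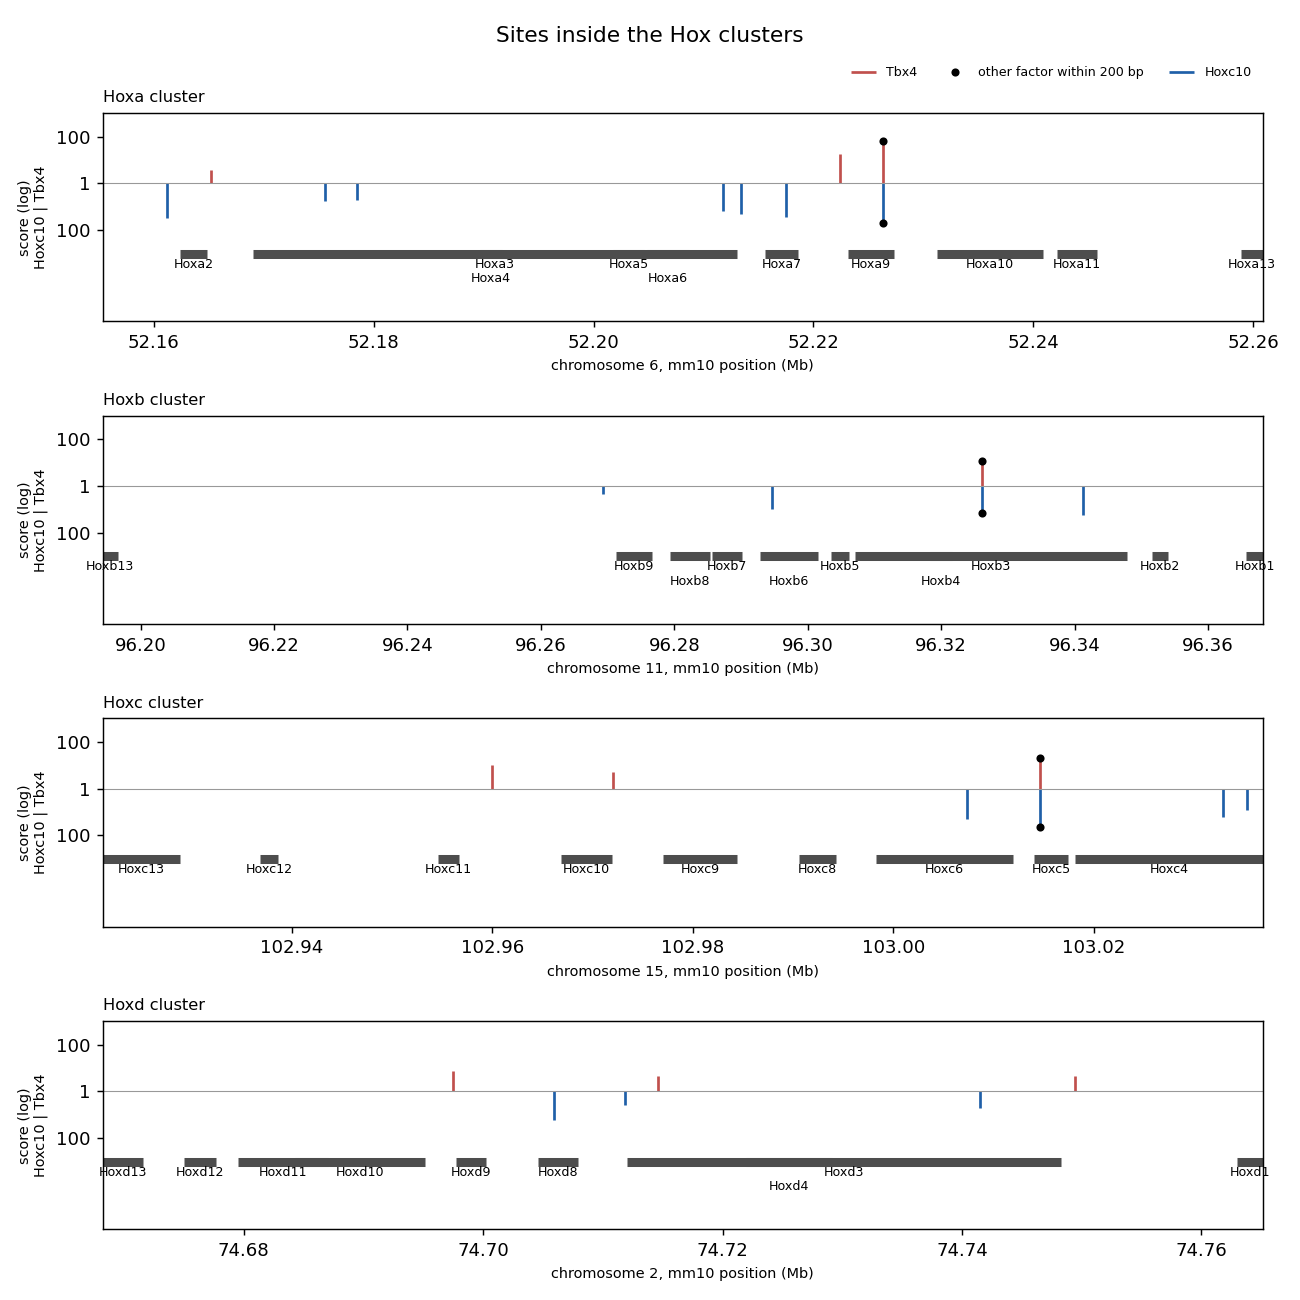
Sites inside the 4 Hox clusters along mm10 (horizontal axes, Mb), with bars up for Tbx4 and down for Hoxc10, their length the MACS2 score of each list on a log scale, and black points for sites with the other factor within 200 bp; grey blocks are protein-coding genes, not all of which are drawn. The 18 Hoxc10 and 10 Tbx4 sites share 3 places.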

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

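The shifts of 5 to 20 kb, the share of the top 50 sites, the use of the 1614 highest Tbx4 sites for gene ends, the test of the higher-scoring sites as the whole of the gene end difference and the recurrence of gene ends in both lists were chosen after the results were seen. The shares of sites in domains of Hox cluster genes (-0.925 percentage points, Tbx4 minus Hoxc10), of Hox cofactors and homeodomain partners (-1.53 points) and of guidance and adhesion genes (-1.43 points) were set apart because the test of the difference between the factors passed after adjustment. With the 1614 highest Tbx4 sites the differences were -0.806, -1.30 and -1.12 points and none passed.

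The share of sites within 1 kb of a gene end was 7.83 points higher for Tbx4. A longer list cannot be the whole cause, since 7.37% of the 1614 highest Tbx4 sites lay there against 5.02% of Hoxc10 sites (Fisher's exact test, p = 0.00678). Weak Tbx4 peaks are a candidate explanation for much of it, as the lower-scoring sites were 2.03 times as often at gene ends as the higher-scoring ones, but the higher-scoring sites of both lists still differed by 2.67 points (Fisher's exact test, p = 0.0151). Open gene ends recovered by any antibody would recur in both lists. Tbx4 sites there had a Hoxc10 site less often than elsewhere (8 of 614 against 511 of 4166, -11.0 points), and so had Hoxc10 sites a Tbx4 site (9.88% against 33.3%, Fisher's exact test, p = 1.66e-22 and 2.26e-06). These are the counts of shared sites at gene ends given above, seen from the other side. Most numbered peaks of both lists were not kept and the Hoxc10 list is the shorter one, so a lack of recurrence does not decide on this explanation. Selection after peak calling that acted on gene ends, and a difference between the factors themselves, also remain open and were not tested.

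Tbx4 and Hoxc10 summits fell within 200 bp of each other at 32.1% of Hoxc10 sites. Regional density of sites alone would give a far lower share, as shifts of only 5 to 20 kb gave 0.256%. Enrichment that does not depend on the antibody remains a possible explanation. Bounds set after the results were seen counted over 80% shared among the 50 highest Hoxc10 sites for it, and under 50% against it. The observed 60% (interval 46.2 to 72.4%) neither reaches 80% nor falls under 50%. Among the 50 highest Tbx4 sites the share was 40% (27.6 to 53.8%). The explanation itself sets no such bounds, and most numbered peaks were not kept, so these shares leave such enrichment open. A library with an unspecific antibody, not used here, would be needed to tell it from binding of both factors at the same places, all the more if the Hoxc10 list was limited to sites seen with both of its antibodies. That both factors occupy common limb elements is a hypothesis, which the rarity of shared sites at gene ends does not decide.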

How the results depend on the processing

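The leaving out of chromosomes X and Y, the shift of 5 to 20 kb, the gene with 5 kb to each side, the leaving out of the 10 highest sites, the 1614 highest Tbx4 sites for gene ends, and the tests of sites inside the Hox clusters with their alternatives were chosen after the data were seen. The overlap of the factors ranged from 23.1% at 100 bp to 38.9% at 1000 bp, was 24.6% in the strictest score class and passed its test under every alternative run. The difference near gene ends was between 2.35 and 11.8 points and passed under every alternative run. The higher scores of shared sites kept their direction and test under every alternative run, but among sites within 1 kb of a gene end, with 8 shared sites in each list, the Hoxc10 difference did not pass (permutation p = 0.655).

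The number of gene lists whose share of sites differed between the factors was 3, and changed to 0 with the 1614 highest Tbx4 sites and to 1 with domains of up to 50 kb; the cause was not tested. It was 2 with 1 site per gene domain. The other alternatives of the main results, 64 in number, stayed on the same side or, for counts of lists, within 1.5 times. The number of lists with more genes with a site than random lists was 10 for Tbx4 and ranged from 9 to 12. For Hoxc10 it was 8 and ranged from 6 to 9. Without X and Y genes the counts were still 10 and 8, but some ratios were lower. For Tbx4, 19.83 limb genes were then expected against 17.85 (ratio 1.765 against 1.961). For muscle genes it was 13.44 against 11.92 (adjusted permutation p = 0.01244 against 0.0028). Of the values of single lists, 270 stayed, 14 no longer passed and 6 passed where the main value did not. Another 28 changed direction, none of them past the threshold in either setting. Adjusted p-values of calls that ended ranged from 0.0552 for limb genes with Hoxc10 to 0.959 for housekeeping genes with Tbx4.

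The changes of direction were as follows. For observed over expected genes with Tbx4 sites, ectoderm genes had 0.359 with the nearest gene, 0.738 with domains of up to 50 kb and 0.465 with the gene and 5 kb to each side, endothelial genes 0.564 and 0.736 with the latter pair, and neural genes 1.19 in the higher-scoring 50%. With Hoxc10 sites, neural genes had 1.499 (nearest gene), 1.62 (50 kb) and 2.48 (5 kb), liver genes 1.63 (nearest gene), 1.70 (50 kb) and 1.36 (higher-scoring 50%), BMP, TGF-beta and Hippo genes 0.95 (higher-scoring 50%) and blood genes 0 (50 kb and 5 kb). For Tbx4 minus Hoxc10 in percentage points, the 1614 highest Tbx4 sites gave 0.372 for limb, 0.248 for identity, 0.62 for cartilage, -0.124 for blood and -0.186 for BMP, TGF-beta and Hippo genes. Domains of up to 50 kb gave 0.0515 for limb, 0.0249 for T-box, 0.0732 for muscle, -0.101 for endothelial and -0.0612 for neural genes. Sites over 1 kb from gene ends gave 0.0521 for limb genes, and 1 site per domain -0.083 for endothelial and -0.0281 for neural genes.

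Not run were the overlap of peak intervals (the lists hold summits of 1 bp), another score column and all motif and k-mer alternatives, for which no genome sequence was used here. No paired analysis was possible because each group has 1 sample. The unknown read depth limits what the shorter Hoxc10 list can show: the absence of a site does not show the absence of binding.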

Other observations

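All tests in this part were chosen after the data were seen. Inside the Hox clusters, Hoxc10 sites kept to one side. None of the 18 had a gene of the paralogue groups 10 to 13 as its nearest gene, where 31.1% of the clusters' length would give 5.59 sites (exact binomial test, p = 0.00163). The split of the groups was chosen after the data were seen and sites within a cluster are not independent. This p-value is therefore no separate support for what was seen. Of the 10 Tbx4 sites 2 were next to such a posterior gene, Hoxc10 and Hoxc11, against 3.11 expected (exact binomial test, p = 0.734), and the difference between the factors was not tested.

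Gene families defined by their symbols, 20 in number and some of them picked because members stood among the genes with the most sites, were compared with random genes of like domain length. Tbx4 sites were found at 9 of 10 genes of the Eya family and its homeodomain partners, Six2 among them (2.78 expected), which act in muscle and mesenchyme precursors, with 10 sites at Eya4, 7 at Eya1 and 6 each at Eya2 and Six2. They were also found at 13 of 22 Eph and ephrin genes (6.45 expected), such as Epha4 with 6 and Efna5 and Epha3 with 5 each. No p-value is given for these groups, because the choice of families drew on genes with many sites and the test would in part restate it. Histone genes, which stand in dense clusters of short genes, had Tbx4 sites at 24 of 101 (11.6 expected, adjusted permutation p = 0.002) and Hoxc10 sites at 1. Olfactory receptor genes had fewer sites of both factors than random genes, with Tbx4 sites at 15 of 1110 (94.4 expected) and Hoxc10 sites at 1 (17.1 expected; adjusted permutation p = 0.002 for each). Protocadherin genes had Tbx4 sites at 6 of 69 (14.4 expected, adjusted permutation p = 0.0453). Members of clustered families share sites and are not independent, so that these p-values are too small. High counts without a family call stood at Tle3, with 17 Tbx4 sites, Zfhx3, with 15 Tbx4 and 9 Hoxc10 sites, and Sox11, with 14 and 2.

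Both sex chromosomes were nearly empty, as X held 13 of the Tbx4 sites (0.272%) and 3 of the Hoxc10 sites (0.186%), although it makes up 6.27% of the genome's length. Chromosome Y, 3.34% of the length, held 0.439% and 0.434%. A lack of called peaks is not the cause for Tbx4, since at least 5.07% of its running peak numbers lie on X. The lowest kept Tbx4 score was 1.34, but the calling limit and the scores of the peaks not kept are unknown. This value thus cannot decide whether a minimum score removed X peaks. Selection between peak calling and deposit may account for the few sites on X and Y: at most 0.568% of the Tbx4 peak numbers of X were kept, against at least 8.92% on any autosome, and at most 7.5% against at least 25.7% for Hoxc10, and on Y at most 3.71% and 4.43%. What the selection was is open, no biological explanation was tested, and the lists say nothing on how much either factor binds genes of these chromosomes.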
